A study of Homo sapiens with 9 samples.

How the data were processed

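H2030 is an established human non-small cell lung cancer line. Per the labels' protocols, its cells were transfected with 1 of 3 siRNA preparations at 20 nmol/L with a lipid reagent. The preparations were a non-targeting pool (control), a custom mix against exon 11a of ENAH (siMENA11a) and a commercial pool against all isoforms of ENAH (siMENA). The control pool and the pool against all isoforms come from different reagent lines, per the labels. ENAH encodes hMENA, an actin regulator, and the isoform that holds exon 11a is called hMENA11a. Each of the 3 groups has 3 libraries, numbered in the labels. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

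Per the labels' protocols, total RNA was treated with DNase, depleted of ribosomal RNA and made into stranded libraries that were sequenced as read pairs on an Illumina instrument. The deposited table holds 1 TPM value (transcripts per 1000000) for each of 29972 genes in each of the 9 libraries, and each library sums to 1000000 within rounding, with values rounded to 2 decimals. The table's name points to merged gene values from RSEM, while kallisto and GRCh37 stand in the list of tools and builds, per the submitters' processing notes, without a role or version. Transcript identifiers in the table are those of RefSeq. The aligner, the counting settings and the use of strand are not given in the sources used here. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting error can be given. All 9 value columns were used, and 0 other columns of per-sample values were found.

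Values were divided by a size factor per library, the median of ratios over 12341 genes with a mean TPM of at least 1 and a value above 0 in every library. This scaling was chosen because TPM of ribosome-depleted total RNA moves with a few abundant transcripts. The 13498 genes with a mean scaled TPM of at least 0.5 were tested on log2(scaled TPM + 0.5) with limma 3.58.1 in R 4.3.3, in 1 fit of 3 group means over 9 libraries (eBayes with a mean trend, no block). Fold changes are on that log2(value + pseudocount) scale, which understates the change of genes with low values. A gene was called where the limma p, adjusted by Benjamini and Hochberg over the genes of a comparison, was under 0.05. The 3 comparisons were siMENA11a against control, siMENA against control and siMENA11a against siMENA, and limma's F test asked whether a gene differed among the 3 groups. Means and SDs are of scaled TPM over 3 libraries, and errors of log2 fold changes are standard errors.

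The 26 gene lists hold 835 entries. Some genes, such as PSMB9, TGFB2 and AXL, are shared between lists, so the lists are not independent. The 21 lists with at least 5 tested members were tested with camera of limma (preset correlation 0.01, adjusted over the 21 lists of a comparison). They cover interferon-stimulated genes, cytosolic nucleic acid sensing, interferon ligands and receptors, antigen presentation, checkpoint ligands, NF-kappaB and lymphotoxin, cytokines, mesenchymal, epithelial and actin genes, and SRF and YAP targets. Others cover S phase, G2 and M phase, histones, p53 targets, stress responses, cholesterol synthesis, hypoxia and glycolysis, RNA interference proteins, ribosomal proteins and abundant nuclear RNAs. The 5 lists not tested were mitochondrially encoded genes, of which 0 are in the table, and markers of leukocytes, fibroblasts, endothelial cells and lung epithelial lineages. For each list the count of called members was also made with p-values adjusted over the list alone.

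Groups, comparisons, their tests, gene lists, the rule for named genes and all alternatives except 2 were chosen before the data were examined. Of the tests of other explanations, 3 on the interferon response (leukocytes, loss of all isoforms and sensing of the duplexes) were chosen after its result was seen. The rule names, for each knockdown against control, the 12 largest rises and 12 largest falls among called genes with a mean scaled TPM of at least 1, no overlap between the libraries of the groups and a symbol that marks no clone, pseudogene, small RNA or histone. It names the 6 highest and 6 lowest for siMENA11a against siMENA, up to 4 members of each list by adjusted p, and a fixed set of genes of the ENAH, interferon, lymphotoxin and epithelial programmes. Some of the genes it names are not reported here. For both knockdowns against the shared controls, the overlap of calls was set beside independent lists and beside 20 simulated pairs of unchanged groups. Each pair shared simulated control libraries, with genes drawn independently of each other.

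Sequence matches of siRNA seeds were searched as all 16384 words of 7 bases in 3' UTRs of GENCODE 29 on GRCh38, for the 11305 tested genes with an annotated 3' UTR (83.8%). The annotated 63-base exon of ENAH was taken as exon 11a from its length, and its 57 distinct 7-base words were compared with the rest. A word was ranked by how far genes that carry it fell, and Fisher's exact test was run in the genes not used to choose it, with the genes split at random into 2 parts. This part used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The siRNA sequences were not used here.

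The limma step was tested on simulated data for siMENA11a against control with 13498 genes. It recovered 56.7% of genes changed by 0.3, 79.1% of those changed by 0.5 and 90.9% of those changed by 1 on the log2 scale, with 10 false calls. The camera step on 13498 simulated genes for siMENA against control recovered a list shifted by -0.2 and called 0 other lists. Those genes were simulated independently of each other, so this does not test lists whose members vary together. In the data the estimated correlation was 0.159 for interferon-stimulated genes and 0.456 for histone genes, above the preset of 0.01. The word search on 11305 genes ranked the planted word first in 20 of 20 simulations from siMENA11a against control.

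Alternatives were pseudocounts of 0.1 and 1, no filter on low values, a filter at a mean of 5, TPM as deposited, quantile normalisation, and TPM rescaled after small and structured RNAs were left out. Others were eBayes without the trend or with robust estimation, a fit of only the 2 groups compared, the replicate number as a block, leaving out each library in turn, and for lists camera with an estimated correlation and fry. The lists were also run on genes without the leading seed words, and with genes that share all values counted once. These 2 were added after the data were seen. Values of single isoforms were not used here, so the level of hMENA11a itself is not reported.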

Results

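Gene expression was compared in H2030 lung cancer cells after transfection with non-targeting siRNA, with siRNA against exon 11a of ENAH, or with siRNA against all isoforms of ENAH. The series asks which programmes inside the tumour cell, with type I interferon signalling and the RNA sensor RIG-I among them, respond to loss of the hMENA11a isoform. There were 3 libraries in each of the 3 groups. Between 12258 and 12520 genes reached 1 TPM in a library. RN7SL transcripts, the RNA component of the signal recognition particle, took 40.2% ± 0.769 (SD, n = 3) of the TPM in control, 44.9% ± 0.487 in siMENA11a and 40.1% ± 0.524 in siMENA. Size factors were 0.995 to 1.04 in control, 0.886 to 0.973 in siMENA11a and 1.06 to 1.09 in siMENA. Without them, the median log2 fold change of all tested genes was -0.11 for siMENA11a against control and -0.20 for siMENA11a against siMENA, so changes are given relative to those medians. On the first principal component (36.2% of the variance) the siMENA11a libraries lay at 33.0 to 34.6, the control libraries at -11.1 to -8.08 and the siMENA libraries at -25.4 to -22.7. Pearson correlations of log values across genes, which are not independent replicates, were 0.978 to 0.985 for the 9 pairs of libraries within a group. They were 0.951 to 0.971 for the 27 pairs between groups, and 0 pairs of libraries held identical values.

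ENAH, the targeted gene, lies on chromosome 1 at 225486835 to 225653142 on the minus strand of GRCh38, and its 63-base coding exon lies at 225504991 to 225505053 of the same build. Scaled ENAH values were 43.6, 43.2 and 44.7 TPM in control libraries 1, 2 and 3. They were 46.7, 47.5 and 48.7 TPM in siMENA11a libraries and 6.89, 7.30 and 7.48 TPM in siMENA libraries. ENAH fell by 2.52 ± 0.038 on the log2 scale under siMENA (limma adjusted p = 4.98e-10). Under siMENA11a the summed ENAH value rose by 0.12 ± 0.038 (adjusted p = 0.0247). That small rise depended on the scaling, with a log2 fold change of -0.014 in TPM as deposited (adjusted p = 0.863). It was no longer called without control 1 (0.11, adjusted p = 0.0648), control 2 (0.11, adjusted p = 0.0756), siMENA11a 2 (0.12, adjusted p = 0.0546) or siMENA11a 3 (0.10, adjusted p = 0.0773). A value summed over isoforms does not measure exon 11a, so it checks the label of siMENA and not that of siMENA11a.

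**Figure D1:**
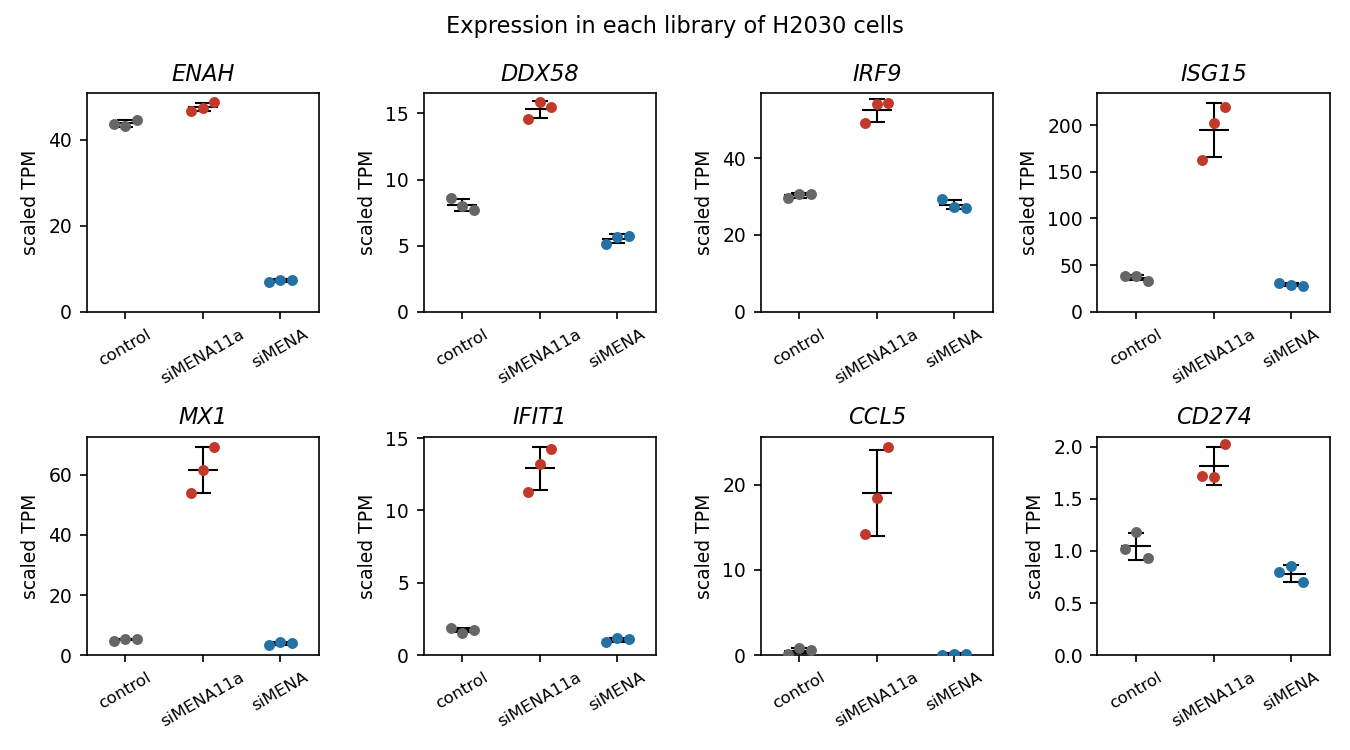
Scaled TPM of ENAH, DDX58, IRF9, ISG15, MX1, IFIT1, CCL5 and CD274, with 1 point per library, bars for the mean of 3 libraries and error bars for the SD in control, siMENA11a and siMENA. ENAH is at 6.89 to 7.48 TPM in siMENA against 43.2 to 48.7 TPM in the other groups, and mean MX1 is 61.6 TPM in siMENA11a against 5.26 TPM in control.

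After transfection with siRNA against exon 11a, interferon-stimulated genes were higher than in control. The chemokine gene CCL5 rose from 0.562 ± 0.329 TPM to 19.0 ± 5.08 TPM (SD, n = 3), a log2 fold change of 4.22 ± 0.26. IFI6, an interferon-induced mitochondrial protein, rose from 38.0 ± 3.19 to 647.4 ± 54.2 TPM (4.07 ± 0.070, adjusted p = 7.36e-10). MX1, a GTPase that blocks viral replication, rose from 5.26 ± 0.31 to 61.6 ± 7.63 TPM (3.43 ± 0.11). The other largest rises were IFI27 (2.67), CYP4F3 (2.62), IFIT1 (2.59), XAF1 (2.44), ISG15 (2.39), PI3 (2.35), IFI44L (2.26), CHAC1 (2.22) and OASL (2.05). CYP4F3 inactivates leukotriene B4, PI3 is a secreted elastase inhibitor, and CHAC1 degrades glutathione and is induced in the integrated stress response. The largest falls were LANCL1 (-2.42), TGFBR2 (-2.25), UBASH3B (-2.18), SAPCD2 (-2.18), PPP1R14C (-2.12), TMEM97 (-2.10), CTSB (-2.08), LIMK1 (-2.04), SUMF1 (-2.04), RHOQ (-2.02), NT5E (-1.96) and HDGF, which lay between RHOQ and NT5E. TGFBR2 encodes the type II TGF-beta receptor, CTSB the lysosomal protease cathepsin B, LIMK1 the kinase that phosphorylates cofilin and NT5E the adenosine-producing enzyme CD73. TGFBR2 went from 91.7 ± 3.65 to 18.9 ± 0.111 TPM, NT5E from 72.1 ± 5.14 to 18.1 ± 0.869 TPM and the growth factor gene HDGF from 460.1 ± 5.03 to 115 ± 8.92 TPM.

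Of the 13498 tested genes, 7503 (55.6%) were called for siMENA11a against control, 3770 higher and 3733 lower, with a median absolute log2 fold change of 0.36. At least 2-fold changes were rarer, with 168 genes higher and 186 lower. The 3 libraries of each group did not overlap for 62.9% of genes, against 10% by chance. The direction of the small changes rests on the scaling, since 1965 genes were higher and 4904 lower in TPM as deposited (28.6% higher against 50.2%), and 4687 were higher and 3111 lower in TPM rescaled without small and structured RNAs (60.1% higher). All 12 of the largest falls carry the word CAAGGAA or CCAAGGA of the 63-base exon in the 3' UTR, as do 4 of the 12 largest rises and 24.1% of all genes searched. Among called falls of at least 2-fold the share was 58.0% of 162 genes searched, and among genes not called 22.3%. Both words were picked because their carriers fell most in this comparison, so these shares are partly built in. In genes not used to pick a word, it marked 44.4% of falls of at least 2-fold and 15.1% of other genes.

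Type I interferon-stimulated genes rose as a group under siMENA11a. Of 54 tested, 48 rose, 5 fell and 1 was not called, and adjusted over the list alone the counts were 48 and 5 (median log2 fold change 0.97). Beside those already given, SAMD9, which restricts poxvirus growth, rose by 1.82 ± 0.067 on the log2 scale. IRF9, a DNA-binding factor of interferon signalling, rose by 0.78, and the antiviral effectors IFIT2 (1.51), IFIT3 (1.39) and OAS1 (0.72) rose as well. The camera adjusted p was 1.61e-18, but the adjusted p = 0.112 with an estimated correlation. Cytosolic nucleic acid sensing genes also rose, with 15 of 25 higher, 6 lower and 4 not called (16 and 6 adjusted over the list alone, median 0.35). DDX58, which encodes RIG-I, rose from 8.09 ± 0.447 to 15.3 ± 0.662 TPM (0.88 ± 0.060, adjusted p = 2.71e-06). IFIH1 (0.98), which encodes MDA5, IFI16 (1.61), DHX58 (1.24) and SAMHD1 (0.98) rose too, while MAVS, the adaptor of RIG-I, fell by 0.35 on the log2 scale and carries a site. The camera adjusted p of the sensing list was 0.0262, and the adjusted p = 0.341 with an estimated correlation. Its call also ended on genes without a leading seed word (adjusted p = 0.112, with 10 higher and 4 lower of 15), an alternative chosen after the data were seen. The median there was 0.36 over 15 members, against 0.35 over 25, so the shift itself was not smaller. IFNB1, which encodes interferon beta, was listed at 0 in 8 of 9 libraries and at 0.08 TPM in siMENA11a 2. CXCL10 was listed at 0.14, 0.14 and 0.19 TPM in siMENA11a and at no more than 0.07 TPM in the other libraries, and neither was tested.

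Proliferation genes fell under siMENA11a. All 40 tested G2 and M phase genes fell (40 also adjusted over the list alone, median -0.52), among them the mitotic transcription factor FOXM1 (-0.88), the kinesin KIF20A (-0.85) and the proliferation marker MKI67 (-0.69). Of 38 S phase genes, 0 rose, 34 fell and 4 were not called (0 and 34 adjusted over the list alone, median -0.52), among them the replication factors GINS2 (-1.14) and MCM7 (-0.65). Replication-dependent histone genes, whose reads can be shared between near-identical copies and are therefore uncertain, fell in 19 of 21 cases, with 1 higher and 1 not called (19 and 1 adjusted over the list alone, median -1.06). HIST1H3B fell by 1.30 and HIST1H1E by 1.17 on the log2 scale. Cholesterol synthesis genes fell in 18 of 24 cases, with 3 higher and 3 not called (19 lower and 3 higher adjusted over the list alone, median -0.36). Among them were the sterol demethylase CYP51A1 (-0.74) and the feedback regulator INSIG1 (-0.99). Camera adjusted p-values were 1.61e-18 for G2 and M phase, 7.97e-13 for S phase, 1.39e-09 for histones and 6.1e-05 for cholesterol synthesis. With an estimated correlation none was called (adjusted p = 0.111, 0.12, 0.341 and 0.385). Sites of the 2 exon words were found in 2 of 39 searched falls of the G2 and M list, 8 of 34 of the S phase list, 0 of 8 of the histone list and 4 of 18 of the cholesterol list.

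NF-kappaB and lymphotoxin, mesenchymal and actin genes shifted down under siMENA11a. In the NF-kappaB and lymphotoxin list, 17 of 29 fell, 4 rose and 8 were not called (17 and 4 adjusted over the list alone, median -0.28). MAP3K14, the kinase NIK of the non-canonical pathway, fell by 1.34 ± 0.051, RELB by 1.07 ± 0.074 and NFKB2 by 0.67 ± 0.052 on the log2 scale. LTB, which encodes lymphotoxin beta, went from 5.29 ± 0.596 to 1.39 ± 0.506 TPM (-1.65 ± 0.30), and its receptor gene LTBR fell by 0.56. Of 36 mesenchymal and matrix genes, 17 fell, 4 rose and 15 were not called (17 and 4 adjusted over the list alone, median -0.19). The matrix protein gene THBS1 fell by 1.92 and fibronectin FN1 by 0.44, while the urokinase receptor PLAUR rose by 0.58. Of 45 actin regulators, 22 fell, 11 rose and 12 were not called (22 and 12 adjusted over the list alone, median -0.08). The actin-capping gene CAPZA1 fell by 1.40, the formin DIAPH1 by 1.10, cofilin CFL1 by 0.64, and the ENAH relatives VASP and EVL by 0.38 and 0.36. Camera adjusted p-values were 0.0147, 0.0147 and 0.0262, and with an estimated correlation the adjusted p = 0.383, 0.433 and 0.341. A filter at a mean of 5 TPM ended all 3 calls (adjusted p = 0.0549, 0.0549 and 0.079), and quantile normalisation ended that of actin (0.112). All 3 calls also ended on genes without a leading seed word (adjusted p = 0.0917, 0.364 and 0.391), where the medians were -0.17, -0.09 and -0.08. That run left out carriers of the siMENA words too and kept 22, 21 and 15 members. The smaller lists may also have ended the calls. Sites were found in 5 of 17, 8 of 17 and 10 of 22 of the falls, with MAP3K14, THBS1, LIMK1 and DIAPH1 among the carriers and LTB, RELB, NFKB2, CAPZA1 and CFL1 not.

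The other tested lists were not called for siMENA11a against control. Of 23 antigen presentation genes, 12 rose and 7 fell (12 and 7 adjusted over the list alone, adjusted p = 0.154), with B2M (0.74) and HLA-F (0.91) higher and the immunoproteasome gene PSMB8 (-1.34) and the peptidase ERAP2 (-1.28) lower. HLA genes can share reads and are uncertain. Of 15 checkpoint ligands, 4 rose and 3 fell (4 and 3 adjusted over the list alone, adjusted p = 0.663). CD274, which encodes PD-L1, rose from 1.04 ± 0.127 to 1.81 ± 0.182 TPM (0.59 ± 0.11, adjusted p = 0.00173), and CD24 fell by 0.58. Interferon ligands and receptors (3 higher, 3 lower of 13, also adjusted over the list alone, adjusted p = 0.793) included IFNAR2 (-0.64) and the inhibitor SOCS3 (0.58). Cytokines (10 higher, 6 lower of 24, the same adjusted over the list alone, adjusted p = 0.409) included IL18 (1.06) and IL6 (-0.57). Epithelial genes (14 higher, 4 lower of 29, the same adjusted over the list alone, adjusted p = 0.0875) included EPCAM (0.80), KRT7 (0.65) and the tight junction gene CLDN1 (-1.04). SRF and YAP targets (14 higher, 20 lower of 38, the same adjusted over the list alone, adjusted p = 0.245) included MYL9 (-1.20), TPM1 (-0.92) and CYR61 (-0.65). Of these falls PSMB8, ERAP2, CD24, IFNAR2, CLDN1, MYL9 and TPM1 carry a site of the exon words, and IL6 and CYR61 do not.

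Stress and RNA lists were mixed as well under siMENA11a. Stress response genes of the unfolded protein and integrated pathways (16 higher, 10 lower of 34, the same adjusted over the list alone, adjusted p = 0.17) included asparagine synthetase ASNS (1.06) and EDEM1 (-0.88). The p53 targets (7 higher, 4 lower of 27, with 5 and 4 adjusted over the list alone, adjusted p = 0.322) included SESN2 (1.73). Hypoxia and glycolysis genes (11 higher, 6 lower of 28, with 12 and 7 adjusted over the list alone, adjusted p = 0.278) included the glucose transporter SLC2A3 (0.87). RNA interference genes (3 higher, 8 lower of 13, the same adjusted over the list alone, adjusted p = 0.0729) included AGO4 (0.77) and DROSHA (-0.42), and were called lower without control 3 (adjusted p = 0.0455) and with no filter (0.0315). Ribosomal protein genes, which share reads with pseudogenes and are uncertain (4 higher, 15 lower of 50, with 3 and 11 adjusted over the list alone, adjusted p = 0.2), included RPLP0 (-1.25), and were called lower in TPM as deposited (0.000591). Abundant nuclear RNAs (5 higher, 1 lower of 18, the same adjusted over the list alone, adjusted p = 0.0649) included GAS5 (0.88), MALAT1 (0.44) and NEAT1 (-0.37). That list was called higher without siMENA11a 3 (adjusted p = 0.0138), with a filter at 5 (0.0483) and in TPM as deposited (0.00824). RPLP0 and DROSHA carry a site of the exon words, and EDEM1 does not.

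After siRNA against all ENAH isoforms, TPM1, ITGB1 and LTB were among the largest falls from control beside ENAH itself. TPM1, an actin-binding tropomyosin, fell from 362.4 ± 7.71 to 61.3 ± 2.27 TPM (SD, n = 3), a log2 fold change of -2.56 ± 0.033 (adjusted p = 2.31e-10). ITGB1, the integrin beta 1 subunit, fell from 565.2 ± 3.01 to 154.1 ± 18.5 TPM (-1.88 ± 0.073), and LTB from 5.29 ± 0.596 to 0.330 ± 0.381 TPM (-2.89 ± 0.30). The other largest falls were KCNMA1 (-2.38), CRLF2 (-1.97), MICAL2 (-1.89), RBM24 (-1.79), IGF2BP3 (-1.77), OXTR (-1.76) and SDC4 (-1.73). MICAL2 oxidises actin, and SDC4 encodes the adhesion receptor syndecan 4. COMMD3-BMI1 (-1.88 ± 0.60, adjusted p = 0.0271) is a read-through transcript that shares reads with its neighbours and is uncertain. Its call ended without control 1 (-1.63), control 3 (-1.98) or siMENA 1 (-1.16), with no filter and with robust eBayes (adjusted p of 0.0517 to 0.0872). The largest rises were S100A9 (2.33 ± 0.36), a calcium-binding inflammatory protein, PLEKHB1 (1.77), SMPDL3B (1.77), STAT4 (1.70), NR4A2 (1.65), DHRS2 (1.63), PI3 (1.60), MSMP (1.57), ARRDC4 (1.51), MMP11 (1.46), DEPTOR (1.44) and CRB3 (1.43).

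For siMENA against control, 6674 of 13498 genes (49.4%) were called, 3196 higher and 3478 lower, with a median absolute log2 fold change of 0.33. Changes of at least 2-fold counted 68 genes higher and 176 lower, and the libraries of both groups did not overlap for 57.6% of genes, against 10% by chance. Higher genes made up 47.9% of calls, 63.4% in TPM as deposited (3979 higher, 2300 lower) and 64.7% in TPM rescaled without small and structured RNAs (4628 higher, 2527 lower). The words CAGAATA, AGAATAA, CAGCGTA and AGCGTAA, all present in ENAH transcripts, mark the 3' UTR of 59.6% of 141 searched falls of at least 2-fold, against 28.3% of all genes searched. Of the largest falls with a searched 3' UTR, 4 of 11 carry one (ENAH, KCNMA1, IGF2BP3 and OXTR), and of the largest rises 1 of 12. The 4 words were picked because their carriers fell most in this comparison, so these shares are partly built in. In genes not used to pick it, CAGAATA marked 41.8% of falls of at least 2-fold and 15.0% of other genes.

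Actin, mesenchymal and serum-response genes fell under siMENA. Of 45 actin regulators, 25 fell, 8 rose and 12 were not called (27 and 9 adjusted over the list alone, median -0.16), with the ENAH-binding protein gene RAPH1 at -1.16 and destrin DSTN at -0.93. Of 36 mesenchymal genes, 19 fell, 6 rose and 11 were not called (20 and 7 adjusted over the list alone, median -0.24). Vimentin VIM went from 1015 ± 17.6 to 532.5 ± 37.3 TPM (-0.93 ± 0.049), the receptor kinase AXL fell by 1.30 and the collagen cross-linking enzyme LOXL2 by 1.09. Of 38 SRF and YAP targets, 21 fell, 11 rose and 6 were not called (22 and 12 adjusted over the list alone, median -0.26), with CYR61 at -0.80. Camera adjusted p-values were 0.000909, 0.000534 and 0.01, and with an estimated correlation the adjusted p = 0.254 for each. Quantile normalisation ended the calls of actin (0.0827) and of SRF and YAP (0.0928). Sites of the 4 words were found in 12 of 25, 6 of 19 and 4 of 21 of the falls, with RAPH1, DSTN and VIM among the carriers and AXL, LOXL2 and CYR61 not.

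Proliferation, glycolysis and stress genes fell under siMENA as well. In the G2 and M list 30 of 40 fell, 1 rose and 9 were not called (30 and 1 adjusted over the list alone, median -0.22), among them anillin ANLN (-0.83) and topoisomerase TOP2A (-0.68). In the S phase list 25 of 38 fell, 2 rose and 11 were not called (26 and 3 adjusted over the list alone, median -0.27), among them thymidylate synthase TYMS (-0.96). Of 21 histone genes, with the same doubt over shared reads, 16 fell, 2 rose and 3 were not called (16 and 2 adjusted over the list alone, median -0.41). Of 28 hypoxia and glycolysis genes, 21 fell, 1 rose and 6 were not called (21 and 2 adjusted over the list alone, median -0.33), with the glycolytic enzyme PGAM1 at -1.64 ± 0.053 and the glucose transporter SLC2A1 at -0.87. Of 34 stress response genes, 18 fell, 6 rose and 10 were not called (18 and 7 adjusted over the list alone, median -0.20), with the transcription factor ATF4 at -0.58 and the chaperone HSP90B1 at -0.63. Camera adjusted p-values in that order were 5.6e-08, 2.77e-06, 0.000307, 2.77e-06 and 0.0194. With an estimated correlation the adjusted p = 0.254, 0.254, 0.382, 0.328 and 0.476. The stress call ended with a filter at 5 (0.058) and with quantile normalisation (0.0757). Sites were found in 10 of 29 searched falls of G2 and M genes, 8 of 25 of S phase genes and 6 of 21 of glycolysis genes, PGAM1 and TOP2A among them.

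Interferon-stimulated, antigen presentation, NF-kappaB and cytokine lists shifted down under siMENA, while the other immune lists were not called. Of 54 interferon-stimulated genes, 24 fell, 6 rose and 24 were not called (24 and 8 adjusted over the list alone, median -0.13). IFI6 fell from 38.0 ± 3.19 to 17.2 ± 0.517 TPM (-1.12 ± 0.070), PSMB9 by 0.64, OAS3 by 0.54 and IFIT1 by 0.51 on the log2 scale, while IFIT3 (-0.10) and IFI27 (0.02) did not pass the test. Of 23 antigen presentation genes, 15 fell, 1 rose and 7 were not called (15 and 2 adjusted over the list alone, median -0.30), with B2M at -0.52 and PSMB8 at -0.52. Of 29 NF-kappaB and lymphotoxin genes, 17 fell, 4 rose and 8 were not called (18 and 4 adjusted over the list alone, median -0.33), with SOD2 at -0.75 and NFKBIZ at 0.74. Of 24 cytokines, 14 fell, 5 rose and 5 were not called (14 and 5 adjusted over the list alone, median -0.32), with TGFB2 at -1.34 and GDF15 at 1.06. Camera adjusted p-values were 0.0194, 0.00184, 0.00295 and 0.0316, and with an estimated correlation the adjusted p = 0.476, 0.254, 0.254 and 0.254. A filter at 5 ended the calls of interferon-stimulated genes (0.1), NF-kappaB (0.058) and cytokines (0.221). The cytokine call also ended without siMENA 2 (0.0537) and on genes without a leading seed word (0.0925). On the latter genes the cytokine median was -0.24 over 17 members, against -0.32 over 24. Sites were found in 5 of 24, 3 of 15, 2 of 17 and 3 of 13 of the searched falls, with IFI6, IFIT1, PSMB8, SOD2 and TGFB2 among the carriers and OAS3, PSMB9 and B2M not.

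The other tested lists were not called for siMENA against control. Sensing genes (8 higher, 8 lower of 25, the same adjusted over the list alone, adjusted p = 0.779) moved in both directions. DDX58 fell from 8.09 ± 0.447 to 5.52 ± 0.34 TPM (-0.51 ± 0.060), MAVS by 0.82 and SAMHD1 by 0.30, while NLRX1 (0.40), IFIH1 (0.30) and DHX58 (0.19) rose. The IFIH1 call ended without any 1 of the control libraries, siMENA 2 or siMENA 3 (adjusted p of 0.054 to 0.069). Interferon receptors (4 higher, 7 lower of 13, the same adjusted over the list alone, adjusted p = 0.18) included IFNGR1 (-1.13), IL10RB (-1.03) and IFNAR1 (-0.61), and were called lower with a filter at 5 (0.0436). Checkpoint ligands (2 higher, 7 lower of 15, the same adjusted over the list alone, adjusted p = 0.0523) included the macrophage checkpoint CD47 (-0.72), LGALS1 (-0.69) and CD276 (0.49). They were called lower without control 3 (adjusted p = 0.032), siMENA 2 (0.0462), siMENA11a 1 (0.0463) or siMENA11a 3 (0.0485), and with no filter (0.0182), TPM as deposited (0.0209), rescaled TPM (0.0242) or only the 2 groups (0.0489). Epithelial genes (10 higher, 8 lower of 29, the same adjusted over the list alone, adjusted p = 0.904) included EPCAM (0.88) and KRT7 (-1.10). The p53 targets (3 higher, 10 lower of 27, the same adjusted over the list alone, adjusted p = 0.24) included ZMAT3 (-0.83) and were called lower on genes without a leading seed word (0.0461), and cholesterol genes (7 higher, 6 lower of 24, the same adjusted over the list alone, adjusted p = 0.698) included TM7SF2 (1.16). RNA interference genes (4 higher, 3 lower of 13, the same adjusted over the list alone, adjusted p = 0.837) included TNRC6B (0.83). Ribosomal protein genes (8 higher, 14 lower of 50, the same adjusted over the list alone, adjusted p = 0.484) included RPS6 (-0.90) and were called higher after quantile normalisation (0.000121). Abundant nuclear RNAs (3 higher, 0 lower of 18, the same adjusted over the list alone, adjusted p = 0.514) included NEAT1 (0.48). MAVS, SAMHD1, IFNGR1, KRT7 and ZMAT3 carry a site of the 4 words, and DDX58, CD47, LGALS1, IL10RB, IFNAR1 and RPS6 do not.

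**Figure D2:**
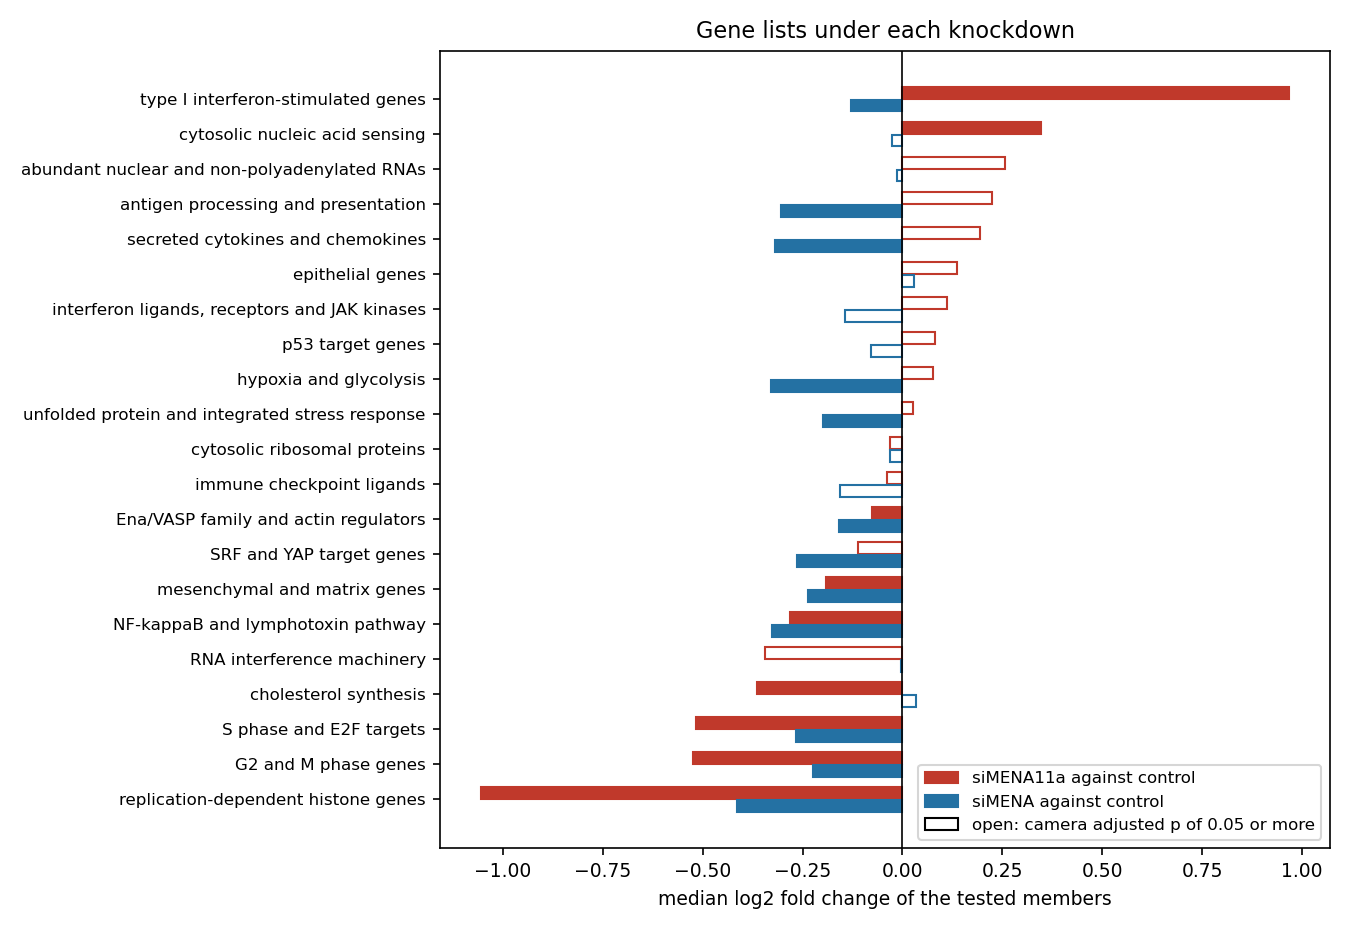
Median log2 fold change of the tested members of 21 gene lists for siMENA11a against control (red) and siMENA against control (blue), with filled bars where the camera adjusted p is under 0.05 and open bars otherwise. Interferon-stimulated genes lie at 0.97 under siMENA11a and at -0.13 under siMENA, and G2 and M phase genes at -0.52 and -0.22.

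The direct comparison of siMENA11a with siMENA asks which genes differ between siRNA against exon 11a and siRNA against all isoforms. Interferon-stimulated genes were higher in siMENA11a, and the highest differences were those of IFI6 (5.19 ± 0.070), CCL5 (4.97 ± 0.26), MX1 (3.79 ± 0.11), IFIT1 (3.10 ± 0.10), ISG15 (2.72 ± 0.10) and LY6K (2.71 ± 0.21). The lowest were LANCL1 (-2.72), S100A9 (-2.47), SUMF1 (-2.33), DHRS2 (-2.25), RHOQ (-2.21) and MARCKSL1 (-2.19). DDX58 was higher by 1.39 ± 0.060, and CD274 by 0.85 ± 0.11 (adjusted p = 0.000138). Of 13498 genes, 7921 (58.7%) were called, 3984 higher and 3937 lower, with 366 and 219 of at least 2-fold. Libraries did not overlap for 65.1% of genes, against 10% by chance, and in TPM as deposited 6321 genes were lower and 24.3% of calls were higher, against 50.3%. In limma's F test 9878 genes (73.2%) differed among the 3 groups.

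Of 54 interferon-stimulated genes, 50 were higher in siMENA11a than in siMENA, 1 was lower and 3 were not called (50 and 1 adjusted over the list alone, median 1.07). Of 25 sensing genes, 15 were higher and 3 lower (15 and 3 adjusted over the list alone, median 0.27). Of 23 antigen presentation genes, 15 were higher and 4 lower (16 and 5 adjusted over the list alone, median 0.42), with B2M at 1.26 and HLA-F at 1.59. Of 24 cytokines, 16 were higher and 4 lower (16 and 4 adjusted over the list alone, median 0.39). Camera adjusted p-values were 2.29e-19, 0.00763, 0.00295 and 0.00957, and with an estimated correlation the adjusted p = 0.196, 0.309, 0.321 and 0.309. Of 34 stress response genes, 22 were higher and 5 lower (22 and 6 adjusted over the list alone, median 0.28), with ATF4 at 0.90 and the cystine transporter SLC7A11 at 1.19. Of 28 glycolysis genes, 21 were higher and 2 lower (21 and 2 adjusted over the list alone, median 0.39), with PGAM1 at 1.80 and SLC2A3 at 1.34. Their camera adjusted p-values were 0.000931 and 1.39e-05, and with an estimated correlation the adjusted p = 0.321 for both. SRF and YAP targets passed narrowly, with 18 of 38 higher and 9 lower (19 and 9 adjusted over the list alone, camera adjusted p = 0.049, adjusted p = 0.321 with an estimated correlation). That call ended without control 1 (0.0524), control 2 (0.0628), control 3 (0.0676), siMENA11a 2 (0.0518), siMENA11a 3 (0.0521) or siMENA 2 (0.0739), in a fit of only the 2 groups (0.0791), and under every other scaling (0.0525 to 0.195).

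Proliferation and sterol genes were lower in siMENA11a than in siMENA. Of 40 G2 and M genes, 30 were lower and 4 higher (31 and 5 adjusted over the list alone, median -0.30), with FOXM1 at -0.75 and the kinase gene BUB1B at -0.71. Of 38 S phase genes, 24 were lower and 6 higher (24 and 6 adjusted over the list alone, median -0.27). Of 24 cholesterol genes, 19 were lower and 2 higher (19 and 2 adjusted over the list alone, median -0.49), with CYP51A1 at -0.84 and HMGCS1 at -0.76. Of 21 histone genes, 18 were lower and 1 higher (18 and 1 adjusted over the list alone, median -0.63), and of 13 RNA interference genes 8 were lower and 2 higher (9 and 3 adjusted over the list alone, median -0.34). Camera adjusted p-values in that order were 4.41e-06, 0.000722, 1.77e-05, 1.14e-05 and 0.0328, and with an estimated correlation the adjusted p = 0.309, 0.321, 0.321, 0.321 and 0.321. The RNA interference call ended in TPM as deposited (0.0895) and after quantile normalisation (0.055). The other 9 lists were not called in this comparison. Their adjusted p-values were 0.154 for interferon receptors, which were called higher with a filter at 5 (0.0322), 0.341 for checkpoint ligands, 0.979 for NF-kappaB and 0.276 for both mesenchymal and epithelial genes. They were 0.541 for actin regulators, 0.119 for p53 targets, 0.574 for ribosomal proteins and 0.159 for abundant nuclear RNAs. In TPM as deposited the ribosomal list was called lower (0.00123) and the nuclear RNA list higher (0.0473), and on genes without a leading seed word mesenchymal genes (0.033) and p53 targets (0.0368) were called higher.

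Between both knockdowns, 2989 genes were called against control in the same direction, 1403 higher and 1586 lower, where independent lists would share 892.6 and 961.9. Another 1395 genes were called in opposite directions, 796 of them higher under siMENA11a and lower under siMENA and 599 the reverse, fewer than the 971.4 and 883.9 of independent lists. All 1395 also differed in the direct comparison, which follows from opposite calls within 1 fit and is no added support. Of the 2989, 1479 differed directly as well. Among the shared falls were LTB (-1.65 and -2.89), THBS1 (-1.92 and -0.88), NT5E (-1.96 and -0.84), TGFB2 (-0.51 and -1.34) and MICAL2 (-1.40 and -1.89). Of these, THBS1, NT5E and TGFB2 carry a leading word of the searches under both siMENA11a and siMENA, and LTB and MICAL2 carry neither. Shared rises included PI3 (2.35 and 1.60), SMPDL3B (1.72 and 1.77), ARRDC4 (1.61 and 1.51) and CRB3 (1.43 and 1.43). Opposite changes included AXL (0.26 and -1.30), IGF2BP3 (0.22 and -1.77), SDC4 (0.44 and -1.73), KRT7 (0.65 and -1.10) and MARCKSL1 (-1.17 and 1.02). Both comparisons use the same 3 control libraries, and 20 simulated pairs of unchanged groups shared 0.05 calls on average and 1 at most. Where no gene changes few calls arise at all, so that count cannot show how far shared controls raised the 2989. Across genes, Pearson's r of the log2 fold changes was 0.32 and Spearman's rho 0.28, against a mean simulated r of 0.49. The covariance was 0.0593 against a simulated 0.0181, a difference of 0.0412. Part of the overlap may come from the shared controls, which are too few to be split. An effect of the non-targeting pool itself would also appear in both comparisons, and the design holds no other control pool.

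Markers of other cell types had medians near 0 in all groups. The median over 20 leukocyte markers was 0.00334 TPM in control, 0.00531 in siMENA11a and 0 in siMENA, and the highest was CD68, a lysosomal protein that tumour lines also express, at 98.9, 126.8 and 44.9 TPM. CD14, a monocyte marker, was at 1.26, 1.85 and 0.817 TPM, called higher under siMENA11a (0.41, adjusted p = 0.0144) and lower under siMENA (-0.42, adjusted p = 0.0154). The siMENA11a call ended in TPM as deposited, after quantile normalisation and without siMENA11a 2 (adjusted p of 0.0513 to 0.0676). Medians were 0.0557, 0.0311 and 0.0465 TPM over 14 fibroblast markers and 0.00655, 0.00343 and 0.00621 TPM over 13 endothelial markers. FBLN1, a matrix gene of the fibroblast list, was at 21.3, 14.2 and 16.4 TPM, and ESAM of the endothelial list was highest in control and at 9.98 TPM in siMENA11a and 5.19 TPM in siMENA. Other markers of these lists rose under siMENA, COL1A1 by 0.88, CDH5 by 0.54 and ACTA2 by 0.46. The ACTA2 call ended without control 2 (0.46), control 3 (0.44) or siMENA 1 (0.30), with adjusted p of 0.0516 to 0.0623. Of 24 lung lineage genes 4 were tested. CAV1, the caveolin of alveolar type 1 cells, fell by 0.92 under siMENA11a and by 0.55 under siMENA on the log2 scale. Its 3' UTR carries leading words of both searches. FOXA1, a transcription factor of lung epithelium, rose by 0.35 and 0.55. In TPM as deposited its rise under siMENA11a was 0.22 (limma adjusted p = 0.0108). CDH1, which encodes E-cadherin, was listed between 0.03 and 0.14 TPM, and ESRP1, an epithelial splicing regulator, at no more than 0.05 TPM.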

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

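The leukocyte, all-isoform and duplex-sensing tests on the interferon response were chosen after the result was seen.

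In each of the following, siMENA11a and siMENA were both called against control in opposite directions, and limma's direct comparison of the knockdowns called the difference. For a single gene the direct call follows from opposite calls within 1 fit and is no added support. On the log2 scale, the difference of siMENA11a minus siMENA was 4.97 for CCL5, 3.79 for MX1, 3.10 for IFIT1, 2.72 for ISG15, 2.64 for ENAH and 1.39 for DDX58. It was -0.49 for EVL and -0.34 for ESRP2, and the median over interferon-stimulated genes was 1.07. With an estimated correlation the camera adjusted p of that list was 0.112 for siMENA11a against control, 0.476 for siMENA against control and 0.196 for the direct comparison, and a filter at a mean of 5 also ended its siMENA call (adjusted p = 0.1). The siMENA11a side of ENAH is the small value that depends on the scaling (-0.014 in TPM as deposited).

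The siMENA side of 5 of these genes depended on the processing. Under siMENA the log2 fold change was -0.75 for CCL5, -0.36 for MX1, -0.33 for ISG15, 0.13 for EVL and 0.16 for ESRP2. MX1 was no longer called without control 2 (-0.33) or siMENA 1 (-0.26) or in TPM as deposited (-0.29, adjusted p = 0.0896). ISG15 was no longer called without control 1 (-0.29), control 2 (-0.30), siMENA 2 (-0.31) or siMENA 3 (-0.29), nor with no filter (adjusted p = 0.0504). Its call also ended in TPM as deposited (-0.24), after quantile normalisation (-0.25) and in rescaled TPM (-0.24), with adjusted p = 0.123, 0.112 and 0.0801. CCL5 was no longer called without control 2 (-0.55), control 3 (-0.70), siMENA11a 2 (-0.76), siMENA 1 (-0.61) or siMENA 2 (-0.80). Its call also ended with a pseudocount of 1 (-0.47, adjusted p = 0.0772), no filter (0.0692), a filter at 5 (0.0588) and eBayes without the trend (0.0502). It was larger, and called, with a pseudocount of 0.1 (-1.62, adjusted p = 0.0189) and in rescaled TPM (-1.21, adjusted p = 0.0173). ESRP2 lost its siMENA call without control 1 (0.16), control 3 (0.12), siMENA 1 (0.13) or siMENA 3 (0.17), and was higher in TPM as deposited (0.24) and rescaled TPM (0.25). Its siMENA11a call (-0.18) ended without control 2 (-0.15) or siMENA11a 3 (-0.14) and in rescaled TPM (-0.13, adjusted p = 0.103), and in TPM as deposited it was at -0.31. EVL lost its siMENA call without control 1 (0.11), control 3 (0.10), siMENA11a 2 (0.13), siMENA11a 3 (0.13) or any siMENA library (0.11 to 0.14). The call also ended with no filter (adjusted p = 0.0637), eBayes without the trend (0.0691), the replicate number as a block (0.0665) or only the 2 groups (0.0558), and was kept in TPM as deposited (0.21) and rescaled TPM (0.22). The direct difference of each of these genes was called in every alternative run.

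The rise of interferon-stimulated genes under siMENA11a is the first pattern to weigh. A trend with GC content or transcript length explained 0.839% of the variance over genes, and after its removal the 48 risers still had a median of 1.04. A median of 0.00531 TPM over 20 markers in siMENA11a argues against leukocytes in the cultures. The list median of -0.13 under siMENA weighs against loss of all hMENA isoforms only if the response was intact there. Under siMENA 8 sensing genes rose and 8 fell, MAVS and DDX58 among the falls. Of 13 interferon ligands and receptors, 4 rose and 7 fell, IFNAR1 among the falls. MAVS carries a site of the siMENA words, so the median cannot decide this. Also open is a response to the duplexes of the exon 11a mix. It cannot be told apart from loss of the isoform because the design holds 1 mix against exon 11a. Loss of hMENA11a itself, the reading the design names, remains a hypothesis. Because siMENA is directed at all isoforms, that one included, the list median under siMENA bears on loss of hMENA11a as a sufficient cause too. It weighs against that cause only if the response was intact under siMENA and the rise does not need the other isoforms to remain. The gene values used here do not give the level of hMENA11a in either knockdown, so this stays open.

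The sharp falls under siMENA11a are the second pattern. After removal of the trend with GC content and length, the 162 falls of at least 2-fold with an annotation kept a median of -1.21. A seed match of the siRNAs is consistent with the data: of all words searched, CAAGGAA of the 63-base exon had rank 1, with 1843 carriers at a mean of -0.13 against 0.018 for other genes. In the genes not used to choose the word, which was CCAAGGA or CAAGGAA, 72 of 162 falls carried it (44.4%) against 15.1% of other genes (one-sided Fisher's exact test, p = 9.78e-19). Many of the falls, LANCL1, TGFBR2, LIMK1 and NT5E among them, may therefore be off-target effects rather than responses to hMENA11a. The falls without a site, and the part of each fall that a site leaves over, could still follow from loss of the isoform. Under siMENA11a 13 words passed a Bonferroni limit over all words, and only the 2 leading ones are counted as sites. A fall without a site may thus carry another match.

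The sharp falls under siMENA are the third. Their median after removal of the same trend was -1.18 over 141 genes. The word CAGAATA, which occurs in ENAH, led the ranking, and in held-out genes 59 of 141 falls carried it (41.8%) against 15.0% of other genes (one-sided Fisher's exact test, p = 2.23e-14). Because 47.0% of all words occur in ENAH transcripts, that occurrence alone says little, while words of the 63-base exon reached rank 1045 at best under siMENA. Seed matches may thus account for part of these falls. TPM1, ITGB1 and LTB, which carry none of the 4 leading words, stay open to a response to loss of hMENA. A difference between the control pool and the pool against all isoforms, which come from different reagent lines, cannot be told apart from it. LTB also fell under siMENA11a, where the summed ENAH value did not fall beyond the scaling. Under siMENA 25 words passed a Bonferroni limit over all words, 17 of them in ENAH. Single genes were searched for the 4 leading words only, so other matches in these genes are not ruled out.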

How the results depend on the processing

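The list alternatives on genes without a seed word, and with genes of identical values counted once, were chosen after the data were seen. The count of called genes stayed within 5863 to 7798 for siMENA11a against control, 5319 to 7155 for siMENA against control and 6185 to 8351 for siMENA11a against siMENA. The lowest count of each came with the filter at a mean of 5, which tests fewer genes. The overlap in the same direction ranged from 2187 (TPM as deposited) to 3185, and the count of the F test from 7517 to 10451. A fit of only the 2 groups compared was not planned for the overlap or the F test. TPM keeps no depth, so what depth limits cannot be given, and values rounded to 2 decimals limit genes near 0. ENAH in siMENA11a against control, called in the reported fit, changed sign to a log2 fold change of -0.014 in TPM as deposited, where library scaling is left out. It was at 0.10 to 0.13 with 1 library left out, and 4 of those runs ended the call (adjusted p of 0.0546 to 0.0773). With camera at an estimated correlation, 0 lists were called in each comparison, where 3, 2 and 2 had an unadjusted p under 0.05. The lowest adjusted p-values were 0.111, 0.254 and 0.196. Fry, which does not compare a list with other genes, called 18 lists for siMENA11a against control, 16 for siMENA against control and 19 for siMENA11a against siMENA. The run without leading seed words kept the 6563 genes with a searched 3' UTR and no leading word of either search. There, 5 lists were called for siMENA11a against control: interferon-stimulated, S phase, G2 and M, cholesterol and histone genes. Actin, mesenchymal, NF-kappaB and sensing lists then had adjusted p-values of 0.391, 0.364, 0.0917 and 0.112, with fewer genes tested. Their medians were -0.08, -0.09, -0.17 and 0.36, against -0.08, -0.19, -0.28 and 0.35 in the reported fit. For siMENA against control 12 lists were called on the 6563 genes, where the cytokine call ended (0.0925, median -0.24) and p53 targets gained one (0.0461). For siMENA11a against siMENA 13 were called, with mesenchymal genes (0.033) and p53 targets (0.0368) gained, and too few RNA interference genes were left to test.

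The genes the rule names for a comparison were run again, other than ENAH and those not reported. Of their 7348 values over 371 gene and comparison pairs, 7236 kept direction and side of the threshold, 73 lost the call, 26 gained it and 13 changed sign, 1 of them called in the reported fit. That one was VASP under siMENA, at 0.0019 after quantile normalisation. OAS1 under siMENA, not called there, changed sign and was called in rescaled TPM (0.089, adjusted p = 0.0394). It also changed sign without being called, at 0.083 in TPM as deposited, 0.098 after quantile normalisation, 0.0018 with only the 2 groups and -0.025 to 0.032 with 1 library left out. IFIT2 under siMENA ranged from -0.24 to 0.0080 with 1 library left out. For siMENA11a against siMENA, AGER was at -0.10 in TPM as deposited and ranged from -0.046 to 0.18 with 1 library left out. The cause of these changes was not tested beyond the scaling itself.

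With the replicate number as a block, 7309, 6386 and 7732 genes were called in the 3 comparisons, 2809 in the overlap and 9643 in the F test. The labels give no meaning to the number, and it did not pair the libraries: correlations of deviations between libraries of the same number were -0.065 to 0.058, 0 of 9 above 0.1, and 3 of 9 libraries correlated best with their own number. The block ended the call of SRF and YAP targets for siMENA11a against siMENA (adjusted p = 0.063) and that of EVL under siMENA (0.0665), added one for COL3A1 under siMENA (0.36), and changed no other call of a list or of the genes so run.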

Other observations

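The tests reported here were planned before the results were seen.

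ATF4 and SLC7A11 rose under siMENA11a and fell under siMENA, while SESN2, CHAC1, HERPUD1 and MTHFD2 did not follow that pattern. ATF4, the transcription factor of the integrated stress response, rose by 0.32 ± 0.041 on the log2 scale under siMENA11a and fell by 0.58 ± 0.041 under siMENA. SLC7A11, which imports cystine for glutathione, rose by 0.69 ± 0.061 and fell by 0.50 ± 0.061. SLC7A11 carries a leading word of the siMENA search in its 3' UTR, so that fall may be off-target, and ATF4 carries none. SESN2, a stress-induced inhibitor of mTORC1, went from 1.07 ± 0.174 TPM in control to 4.71 ± 0.598 TPM in siMENA11a and was at 0.993 ± 0.269 TPM in siMENA (n = 3 each, adjusted p = 0.692). CHAC1 (2.22 and 0.37) and HERPUD1 (0.45 and 0.21) rose in both. MTHFD2, a mitochondrial folate enzyme that ATF4 also drives, fell in both (-0.14 and -0.49). Genes named in the hypoxia list moved in both directions under siMENA11a, with the stress-induced NDRG1 (0.65), the demethylase KDM3A (0.56) and the collagen prolyl hydroxylase P4HA1 (0.49) higher and the glycolytic ENO1 (-0.31) lower. Under siMENA, NDRG1 (-0.16), P4HA1 (-0.14) and ENO1 (-0.54) fell. ENO1 was at -0.32 under siMENA after quantile normalisation.

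COL1A1, a fibrillar collagen chain, fell from 7.72 ± 0.528 to 6.38 ± 0.156 TPM under siMENA11a and rose to 14.6 ± 0.871 TPM under siMENA. The difference of siMENA11a minus siMENA was -1.13 ± 0.060 on the log2 scale. Of the TGF-beta genes, the receptor gene TGFBR2 fell by 2.25 under siMENA11a and by 0.48 under siMENA. The ligand gene TGFB2 fell by 0.51 and by 1.34, and TGFB1 fell by 0.34 under siMENA and was at -0.07 (adjusted p = 0.106) under siMENA11a. GDF15, a stress-induced cytokine of the same family, rose by 0.22 and by 1.06. TGFBR2 and TGFB2 carry a word of the 63-base exon in the 3' UTR, and TGFB2 also carries a leading word of the siMENA search.

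For each comparison of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real splits called 7503, 6674 and 7921 genes, and the highest of the other splits called 1, 2 and 1. For the F test among 3 groups, 1 of 100 splits drawn, the real one, gave as many genes as the 9878 called. The highest other split gave 3719, so a chance assignment of these libraries to groups is unlikely to give that count. If the libraries of a group came from 1 culture, no split can separate the siRNA from a difference between cultures.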
